A study of Homo sapiens with 9 samples.

How the data were processed

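RNA was measured in HEK293T cells, a human embryonic kidney line, in which SRRM2 had been knocked out and an SRRM2-IDR construct put back by piggyBac transposition. Per the labels there were 3 constructs, WT, SA and SD, with 3 samples labelled for each, and the lines were obtained as sorted clonal populations. Per the labels' protocols, libraries came from a stranded mRNA kit and were read on a DNBSEQ-T7 sequencer. The submitters' processing notes name Trimmomatic 0.36 and edgeR 3.12.1 without a role, so these were tools of the authors. The aligner, the splicing caller and the genome build are not given in the sources used here.

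The authors deposited one table for SA against WT and one for SA against SD, with a splicing event in each line. Per the file headers, a line holds the gene, the event type, the coordinates, the counts of inclusion and of skipping junction reads in each library, the effective length of each form, the inclusion levels, a p-value and an FDR. The deposited difference of inclusion level is a score that equals the mean of SA minus the mean of the other group, as the authors' own levels bear out. The deposited p-values and FDRs are the authors' own, and the test behind them is not named per the file headers. Counts of several libraries share a cell, with no replicate numbers, so replicates are named here by their position in the cell. The WT cells hold 2 values although 3 samples are labelled WT, and which 2 they are is not stated. Inclusion levels recomputed from the deposited counts and lengths matched the authors' levels to 5e-04 of a fraction.

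The tables hold only part of what the authors tested. The largest p-value listed was 0.0499 in both tables, and the smallest absolute difference was 10.1 percentage points. The number tested was estimated from the deposited FDRs and p-values, since a Benjamini-Hochberg FDR divided by its p-value is the number of events divided by the rank, except where a later rank sets the FDR. For each event type the estimate was the smallest whole number found that made the ranks whole, to within 0.001, for as many of the listed events of lowest p-value as the best candidate or nearly so. It did so for 10 to 19 of the 20 events used per type, and a multiple of it would do so too. The estimates summed to 57732 events for SA against WT, of which 41899 were cassette exons, and 63605 for SA against SD, of which 46341 were cassette exons.

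Events with a mean of at least 10 inclusion plus skipping reads per library were tested. In each event the share of inclusion reads was compared between groups by a two-sided quasi-binomial F test. The dispersions were moderated across events with squeezeVar of limma 3.58.1 in R 4.3.3 and kept at 1 or above. The prior dispersion was 1.20 with 9.02 degrees of freedom for SA against WT, and 1.34 with 227 for SA against SD. P-values were adjusted by Benjamini-Hochberg within each event type over the estimated number of events the authors had tested, with unlisted events entered at p = 1. An event was called at an adjusted p under 0.05 and a difference of at least 10 percentage points. The count-model test planned before the data were examined, a quasi-likelihood test of edgeR, was not run. The quasi-binomial test of the same counts per library took its place. The planned adjustment over the listed events alone was replaced, after the data had been seen, because the listed events were already selected on their p-value, and its counts are given with the other alternatives.

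On simulated data drawn from the tested events, the test for SA against WT, run on 1013 events, found 3 of 4 changes of 20 points and 11 of 11 changes of 40 points in events with at least 50 reads. In events with 10 to 50 reads it found 19 of 39 changes of 40 points, and at 10 points it found 0 of 42 and, with at least 50 reads, 0 of 8. For SA against SD, run on 913 events, it found 5 of 8 changes of 20 points and 3 of 3 of 40 points in events with at least 50 reads. In events with 10 to 50 reads it found 27 of 47 changes of 40 points, and at 10 points 0 of 43 and, with at least 50 reads, 1 of 7. No unchanged simulated event was called in either comparison.

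Genes were named by a rule fixed before the data were examined. It takes the 12 events higher and the 12 lower in SA with the largest difference among those called. All libraries of one group had to lie on one side of the other group, with at least 20 reads in every library and 1 event per gene. To these it adds up to 4 genes in each of 14 gene lists, and SRRM2. Because few events were called, the same rule was also applied to events past an FDR of 0.05 in the authors' deposited table, and these are named as such. Events past that threshold in both tables, the further called events of HNRNPA2B1 and PLD3 and the shared event with SA between the other groups were named outside the rule, after their values had been seen. A result that this rule would name is not reported here. Gene lists were tested with Fisher's exact test and exon lengths with permutation tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

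Starts in the files count from 0, since the length of all 946 and 811 short cassette exons then equals the gap between the lengths of the forms; starts are printed here from 1. Of the 2261 events listed for SA against WT whose gene was found in RefSeq, 94.7% lay inside the GRCh38.p14 span of that gene. Of the 2011 such events for SA against SD 94.2% did. No genome sequence was used, so splice sites and base composition were not analysed here. Gene expression was not analysed here, as the tables hold splicing events alone. No 2 libraries of a group held the same reads, and the read counts of every pair over the tested events differed by more than sampling noise (chi-square over degrees of freedom from 1.24 to 1.44). Nothing in the labels says that replicates came from separate cultures, so p-values measure at most the spread between these libraries, which may be technical. For NASP, SNRPD1 and SRRM2 the dispersion stood at its floor of 1, so the spread was taken to be that of read sampling. For SA against SD the 227 prior degrees of freedom held each dispersion close to the prior of 1.34. The priors came from events already selected on their p-value. Clone and construct cannot be separated, as the labels give no clone for any sample. Alternatives covered the test, the read filter, the thresholds, the adjustment, the dispersion and each library left out. The intervals of shares are 95% Wilson intervals and cover counting error alone.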

Results

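Splicing was compared between HEK293T lines without their own SRRM2 that carried an SRRM2-IDR construct in the form WT, SA or SD, names that the labels do not spell out. SRRM2 is a large serine- and arginine-rich protein of nuclear speckles, and the series concerns phosphorylation and speckle networks. SA was set against WT with 3 and 2 libraries and against SD with 3 and 3. The measure was the inclusion level, the share of transcripts that carry the alternative exon, intron or splice-site segment, from reads across the junctions. The listed events of the SA against WT table held between 52827 and 61384 junction reads per library, and those of the SA against SD table between 33520 and 38521. The median listed event had 8 or 9 reads per library.

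The first comparison asked how splicing in the SA line differed from that in the WT line. SRRM2 itself carried a called event. A 108-nt cassette exon of SRRM2 (ENSG00000167978) at chromosome 16, 2757472 to 2757579, had an inclusion level of 84.0% ± 0.571 (SD, n = 3) in SA and 94.8% ± 0.159 (SD, n = 2) in WT. It fell by 10.8 percentage points, with an adjusted p of 0.000275 in the limma-moderated quasi-binomial test. The SA libraries stood at 83.6%, 83.7% and 84.6%, and the WT libraries at 94.7% and 94.9%. The reads behind these levels differed in kind, because the SA libraries held 989, 986 and 1169 inclusion reads and the WT libraries 3051 and 3125. Skipping reads were 106, 105 and 116 in SA and 94 and 92 in WT. The table does not tell reads of the construct from reads of the chromosomal gene, so these values check the labels only in part.

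**Figure D1:**
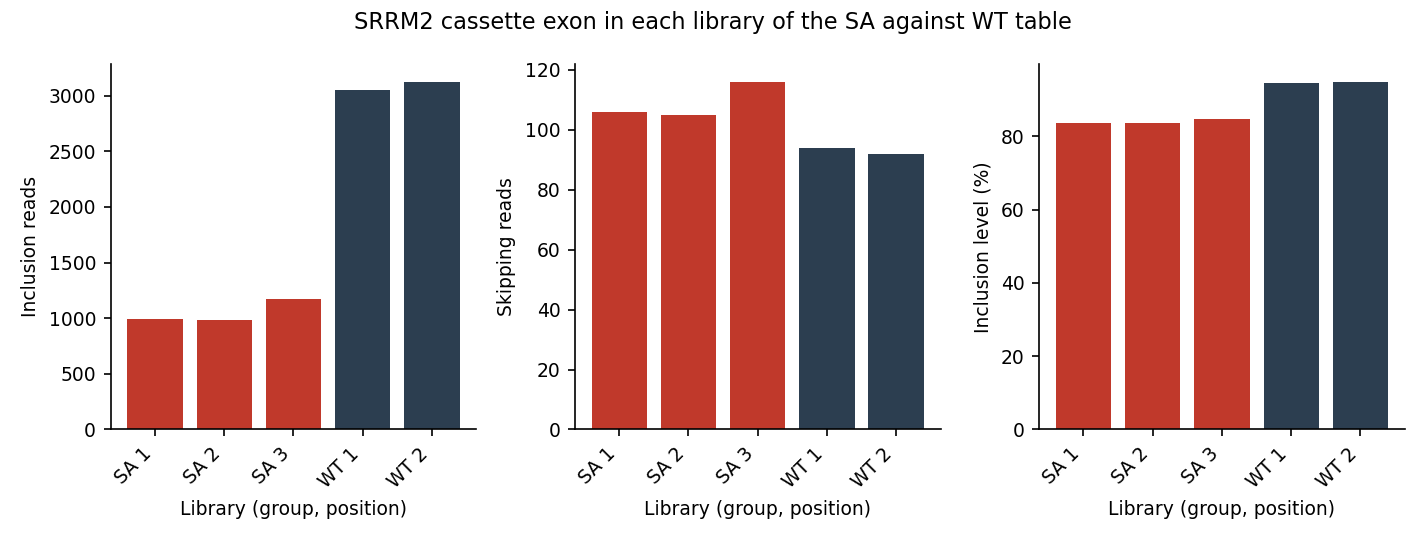
SRRM2 cassette exon in each library of the SA against WT table, with bars for inclusion reads, skipping reads and the inclusion level in percent; replicate numbers are positions in the table. Inclusion reads lie between 986 and 1169 in SA and at 3051 and 3125 in WT, while skipping reads lie between 92 and 116 in all libraries.

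Another 3 events were called between SA and WT. The 1017-nt exon of NASP (ENSG00000132780), a histone chaperone, at chromosome 1, 45607321 to 45608337, rose from 42.8% ± 0.270 (SD, n = 2) in WT to 53.8% ± 0.257 (SD, n = 3) in SA. Its adjusted p was 1.10e-05 in the limma-moderated test, and at least 5830 reads per library lay behind it. Pairs of mutually exclusive exons changed in SNRPD1, a core Sm protein of the spliceosomal snRNPs, and in HNRNPM, an hnRNP protein. The form that the table counts as inclusion was at 56.1% ± 0.419 (SD, n = 3) in SA and 67.0% ± 0.956 (SD, n = 2) in WT for SNRPD1 on chromosome 18. For HNRNPM on chromosome 19 it was at 56.8% ± 2.50 (SD, n = 3) in SA and 67.3% ± 1.72 (SD, n = 2) in WT. The adjusted p values were 0.000709 and 0.0211 in the limma-moderated test, and the header does not define which exon of such a pair is the inclusion form. The table thus held 4 calls, 1 higher and 3 lower in SA, among 1013 tested events of 839 genes, and 474 events had an unadjusted p under 0.05. No event was called by limma on the logit of inclusion levels, where 433 had an unadjusted p under 0.05. None was called without SA replicate 3, where the adjusted p of SRRM2 was 0.454 in the limma-moderated test. The SRRM2 difference in that fit was −11.1 points, and the prior degrees of freedom were 3.94. Without WT replicate 2 the count was 7.

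**Figure D2:**
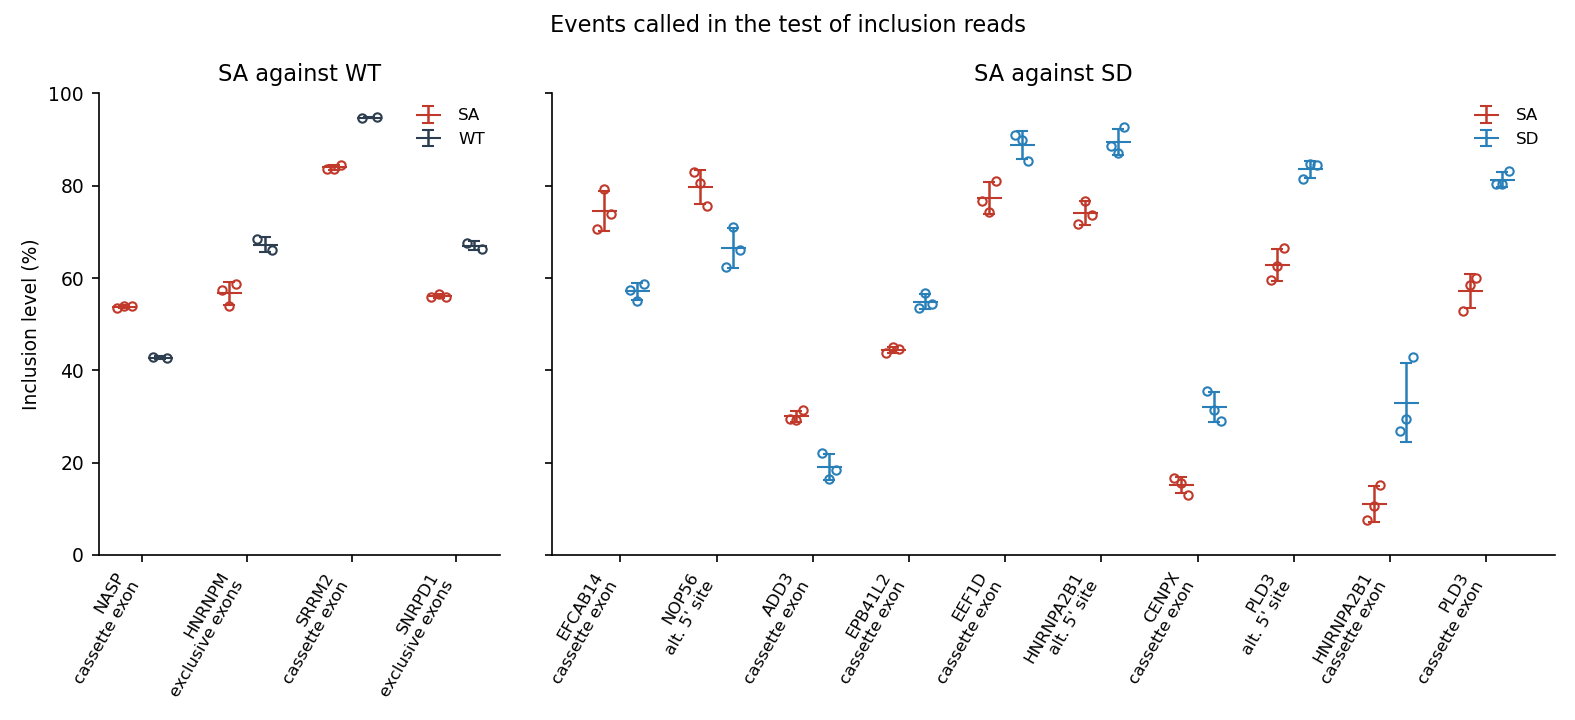
Inclusion level in percent of every event called here, with open circles for libraries, horizontal bars for group means and whiskers for the SD; SA is red, WT dark and SD blue. The 4 events of SA against WT and the 10 of SA against SD show groups whose libraries do not overlap.

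Events past the authors' own threshold were more numerous. The authors' deposited table gave an FDR under 0.05 to 325 events of 284 genes, 142 higher and 183 lower in SA, and 98 of these passed the read filter, 40 higher and 58 lower. Among those with at least 20 reads in every library, all 36 had libraries of SA and WT that did not overlap; for 3 against 2 libraries chance gives this in 20% of events, and the events were selected for a difference. Lower in SA by this measure was a 36-nt exon of PET100, a factor of cytochrome c oxidase assembly, with 50.4% ± 0.340 (SD, n = 3) in SA and 82.9% ± 10.0 (SD, n = 2) in WT. A 115-nt exon of SNRPD2, another Sm protein, had 63.8% ± 13.5 (SD, n = 3) and 92.9% ± 10.1 (SD, n = 2). A 96-nt exon of BAZ1A, a subunit of chromatin remodelling complexes, had 61.2% ± 5.73 (SD, n = 3) and 84.7% ± 8.40 (SD, n = 2). An alternative 3′ splice-site segment of UPF3A, a nonsense-mediated decay factor, had 10.3% ± 1.94 (SD, n = 3) and 31.2% ± 7.52 (SD, n = 2). The others lower in SA were in AAMDC, SLC44A1, NR2C1, PIGA, FZD6, FNBP1, ENTPD6 and CUTC, with differences from −32.1 points in AAMDC to −16.6 points in CUTC. Higher in SA was an intron of RPGR, a ciliary protein, with 95.0% ± 5.13 (SD, n = 3) and 66.6% ± 10.3 (SD, n = 2). Its retained form spans chromosome X, 38287094 to 38288041, both flanking exons included. A 137-nt exon of MCCC1, an enzyme of leucine breakdown, had 95.9% ± 3.56 (SD, n = 3) and 74.2% ± 3.89 (SD, n = 2). A 231-nt exon of TCOF1, a nucleolar protein of ribosome biogenesis, had 89.8% ± 0.630 (SD, n = 3) and 74.2% ± 11.4 (SD, n = 2). SDF2, R3HDM4, COQ7 and SH3GLB2 were also higher, by 18.0, 16.8, 15.1 and 11.6 points. Single libraries weighed on 3 of these values. The difference of TCOF1, 15.6 points, was 23.7 points without WT replicate 1 and 7.59 points without WT replicate 2, that of SH3GLB2 was 5.90 points without WT replicate 1, and that of NR2C1, −21.7 points, was −11.8 points without SA replicate 2. Apart from NASP, the events named in this paragraph had an adjusted p of 1 in the limma-moderated test. In the authors' deposited table their FDR lay between 0.000174 for AAMDC and 0.0422 for TCOF1.

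**Figure D3:**
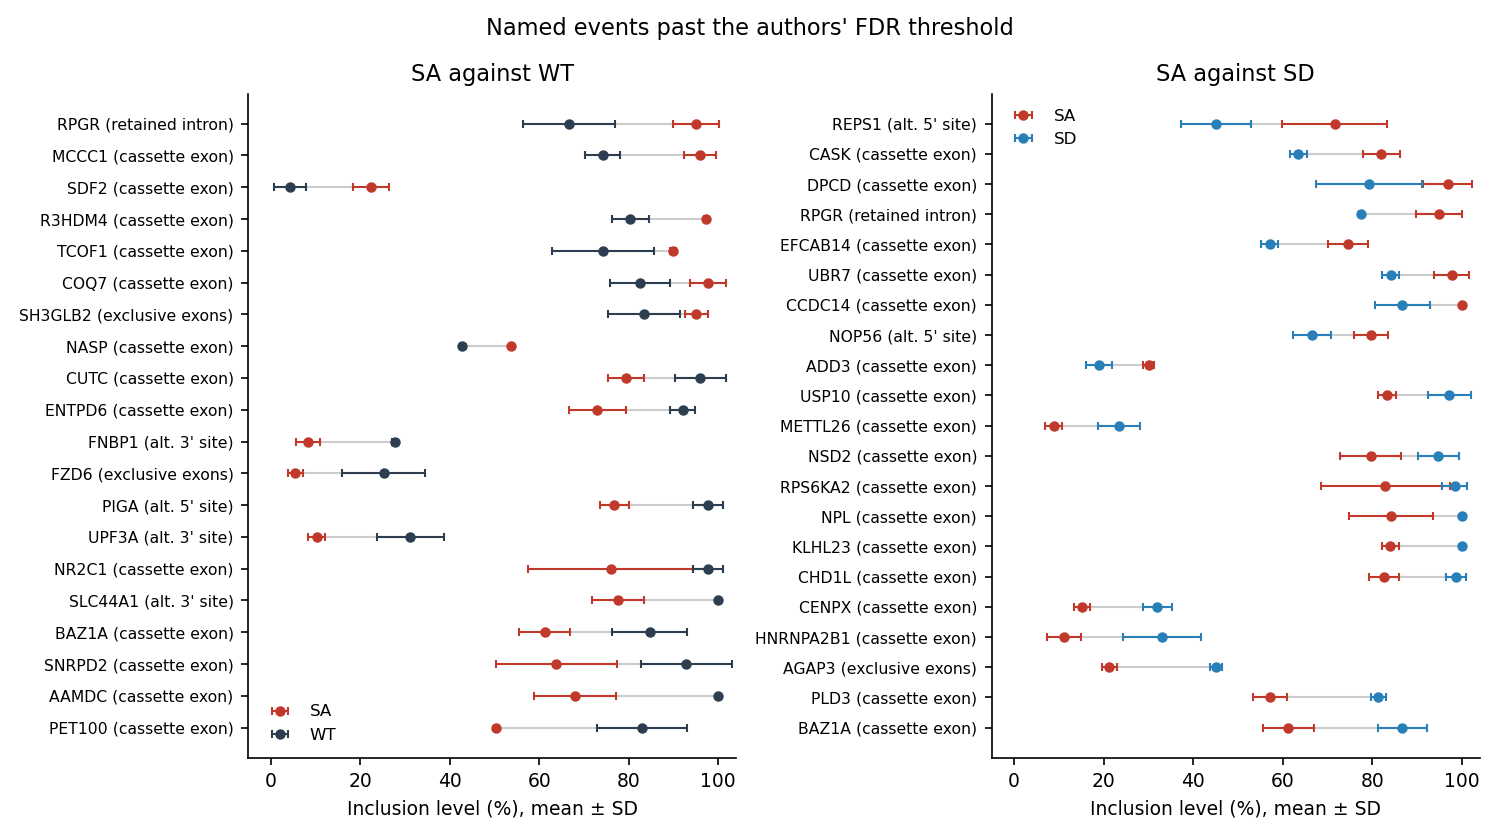
Inclusion level in percent, as mean ± SD of the libraries, of the named events past the authors' FDR threshold, sorted by SA minus the other group; SA is red, WT dark and SD blue. PET100, with 50.4% in SA and 82.9% in WT, and BAZ1A, with 61.2% in SA and 86.7% in SD, stand at the low end, RPGR and REPS1 at the high end.

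SRRM2, HNRNPM and SNRPD1 were the genes called between SA and WT that belonged to a gene list, and NASP belonged to none. SRRM2 was the gene knocked out and put back as a construct, whose reads cannot be told apart here. Its counts in the lists below therefore say nothing about other SR proteins or speckle components. Called genes were 1 of 4 tested SR proteins and 1 of 5 tested nuclear speckle components, in both cases SRRM2, 1 of 2 hnRNP proteins, HNRNPM, and 1 of 8 core spliceosome proteins, SNRPD1. Tested genes are those with a listed event that passed the read filter, so they were already selected on p-value and difference. The hnRNP list holds 30 genes and the core spliceosome list 69, so these are not shares of whole lists. No list passed, with a smallest adjusted p of 0.166 in Fisher's exact test over the 14 lists and both comparisons. Over events past the FDR of the authors' deposited table, 2 of 5 speckle components (SRRM2 and THRAP3) and 2 of 8 core spliceosome proteins (SNRPD1 and SNRPD2) were found, with adjusted p 0.849 for both in Fisher's exact test. The list of SR protein kinases and phosphatases gave 1 of 3 genes, PPP1R8, a phosphatase regulator found in speckles. It had a mutually exclusive pair at 44.5% ± 2.50 (SD, n = 3) in SA and 57.9% ± 2.17 (SD, n = 2) in WT. Chromatin modifiers gave 2 of 20 genes (CHD6 and BRD9), DNA repair 1 of 10 (FANCG) and nonsense-mediated decay 1 of 1 (UPF3A). None was found among 10 genes of mitosis and centrosome, 16 of actin cytoskeleton and vesicle traffic, 4 apoptosis regulators, 3 of the transcription machinery, 2 nervous-system splicing regulators and 1 stress-response gene. Adjusted over the list alone, 4 events of the speckle list, 3 of the core spliceosome list and 2 of the DNA repair list passed. The lists of hnRNP proteins, SR proteins, SR protein kinases and phosphatases, nonsense-mediated decay, stress response and transcription machinery had 1 each and the other lists 0, all from a table that lists only p-values under 0.05.

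The second comparison asked how splicing differed between the SA and SD lines, and 10 events of 8 genes were called, 3 higher and 7 lower in SA. HNRNPA2B1, an hnRNP protein that binds RNA and regulates splicing, carried 2 of them, which share their skipping reads. Its 136-nt exon at chromosome 7, 26190993 to 26191128, fell from 33.0% ± 8.63 (SD, n = 3) in SD to 11.1% ± 3.85 (SD, n = 3) in SA. Its alternative 5′ splice-site segment fell from 89.5% ± 2.86 (SD, n = 3) to 74.0% ± 2.59 (SD, n = 3), with an adjusted p of 1.79e-07 in the limma-moderated test. PLD3, a lysosomal protein of the phospholipase D family, also carried a pair with shared skipping reads, and its 213-nt exon at chromosome 19, 40365718 to 40365930, fell from 81.3% ± 1.64 (SD, n = 3) to 57.2% ± 3.73 (SD, n = 3). A 54-nt exon of CENPX, a centromere and DNA repair protein, fell from 32.0% ± 3.27 (SD, n = 3) to 15.1% ± 1.79 (SD, n = 3). Exons of EEF1D, a translation elongation factor subunit, and EPB41L2, a membrane skeleton protein, fell by 11.4 and 10.4 points. Exons of EFCAB14 and of ADD3, an adducin of the membrane skeleton, rose by 17.5 and 11.0 points in SA. An alternative 5′ splice-site segment of NOP56, a core protein of box C/D snoRNPs, rose from 66.5% ± 4.31 (SD, n = 3) to 79.7% ± 3.74 (SD, n = 3). The adjusted p of the 10 events ran from 1.79e-07 for the splice-site segment of HNRNPA2B1 to 0.0101 for the exons of PLD3, HNRNPA2B1 and EEF1D in the limma-moderated test. SRRM2 was not listed in this table, which holds only events with a p-value under 0.05 and a difference above 10 points.

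The call count of the second comparison depended on the test. It was 10 of 913 tested events, with 514 at an unadjusted p under 0.05. No event was called by limma on the logit of inclusion levels, where 442 had an unadjusted p under 0.05, or without SA replicate 2. It was 1 without SD replicate 2 and 5 without SA replicate 1. Adjusted over the listed events alone, as first planned, it was 140.

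Past an FDR of 0.05 in the authors' deposited table were 329 events of 283 genes, 146 higher and 183 lower in SA, and 112 of them passed the read filter. Of the 47 with at least 20 reads in every library, 40 had groups that did not overlap. For 3 against 3 libraries chance gives this in 10% of events, but these events too were selected for a difference. BAZ1A had the lowest difference of those named in this paragraph, with 61.2% ± 5.73 (SD, n = 3) in SA and 86.7% ± 5.44 (SD, n = 3) in SD for the same 96-nt exon as before. AGAP3 had a mutually exclusive pair at 21.3% ± 1.63 (SD, n = 3) and 45.1% ± 1.39 (SD, n = 3). A 125-nt exon of NSD2, a histone H3 lysine methyltransferase, had 79.6% ± 6.78 (SD, n = 3) and 94.8% ± 4.66 (SD, n = 3). CHD1L, KLHL23, NPL, RPS6KA2, METTL26 and USP10 were lower in SA by measured differences from −16.1 to −13.9 points. On the higher side, a 69-nt exon of CASK, a scaffold kinase, had 82.0% ± 4.20 (SD, n = 3) in SA and 63.5% ± 1.91 (SD, n = 3) in SD. REPS1, DPCD, RPGR, UBR7 and CCDC14 were higher in SA by 26.5, 17.6, 17.6, 13.6 and 13.3 points. The difference of RPS6KA2, −15.5 points, was −7.45 points without SA replicate 2, and that of DPCD was 11.2 points without SD replicate 3. The events named in this paragraph did not pass the limma-moderated test, with adjusted p from 0.297 for REPS1 to 1.

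Among the lists, 1 of 2 tested hnRNP proteins (HNRNPA2B1) and 1 of 12 genes of actin cytoskeleton and vesicle traffic (EPB41L2) were called between SA and SD, with adjusted p 0.166 and 0.574 in Fisher's exact test. Past the FDR of the authors' deposited table were 3 of those 12 genes (EPB41L2, PICALM and SEC16A), all lower in SA, with adjusted p 0.849 in Fisher's exact test. The same threshold gave 2 of 14 genes of mitosis and centrosome, CENPK among them. It also gave 2 of 21 chromatin modifiers (NSD2 and KAT2A), 1 of 5 SR proteins (RSRC1), 1 of 3 SR protein kinases and phosphatases (SRPK1) and 1 of 2 nervous-system splicing regulators (CELF1). None was found among 9 DNA repair genes, 6 of the transcription machinery, 3 of nonsense-mediated decay, 2 core spliceosome proteins, 2 apoptosis regulators and 1 stress-response gene. No speckle component could be tested here, and in the other lists too the genes tested were only those with a listed event. Adjusted over the list alone, 12 events of the mitosis list, 10 of the chromatin list, 6 of the hnRNP list, 4 of the SR protein list and 3 of the list of actin cytoskeleton and vesicle traffic passed, from a table selected on its p-values. The lists of DNA repair, apoptosis regulators and SR protein kinases and phosphatases had 2 each. Those of the core spliceosome, nonsense-mediated decay, nervous-system splicing regulators and stress response had 1 each, and that of the transcription machinery 0.

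By event type, the tested cassette exons had a median difference of −11.1 points between SA and WT, where 280 of 638 were higher in SA (43.9%, Wilson interval 40.1% to 47.8%). Between SA and SD the median was −10.8 points, with 271 of 607 higher (44.6%, Wilson interval 40.7% to 48.6%). Over all listed cassette exons, with no read filter, 742 of 1535 were higher in SA than in WT (48.3%, Wilson interval 45.8% to 50.8%), an interval that includes an even split. Against SD 634 of 1349 were higher (47.0%, Wilson interval 44.3% to 49.7%). Events are not replicates, and some share skipping reads, so these intervals do not test for a lean in either direction. Both comparisons also used the same SA libraries. Retained introns had medians of 15.1 and 11.2 points, with 17 and 15 of 26 higher in SA; without a read filter the SA against SD median was −10.6 points. Since each listed difference exceeds 10 points in size, a median moves across that gap with few events. Cassette exons past the authors' threshold did not differ detectably from the other tested ones in length or in the share divisible by 3. Those other exons were also listed for a low p-value and a difference above 10 points, so no comparison with unaffected exons was possible. Median lengths against WT were 129.5 nt for 30 higher and 115.5 nt for 32 lower exons, beside 114 nt for the 561 others, and adjusted p over the 8 tests ranged from 0.714 to 1 in permutation and Fisher's exact tests.

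**Figure D4:**
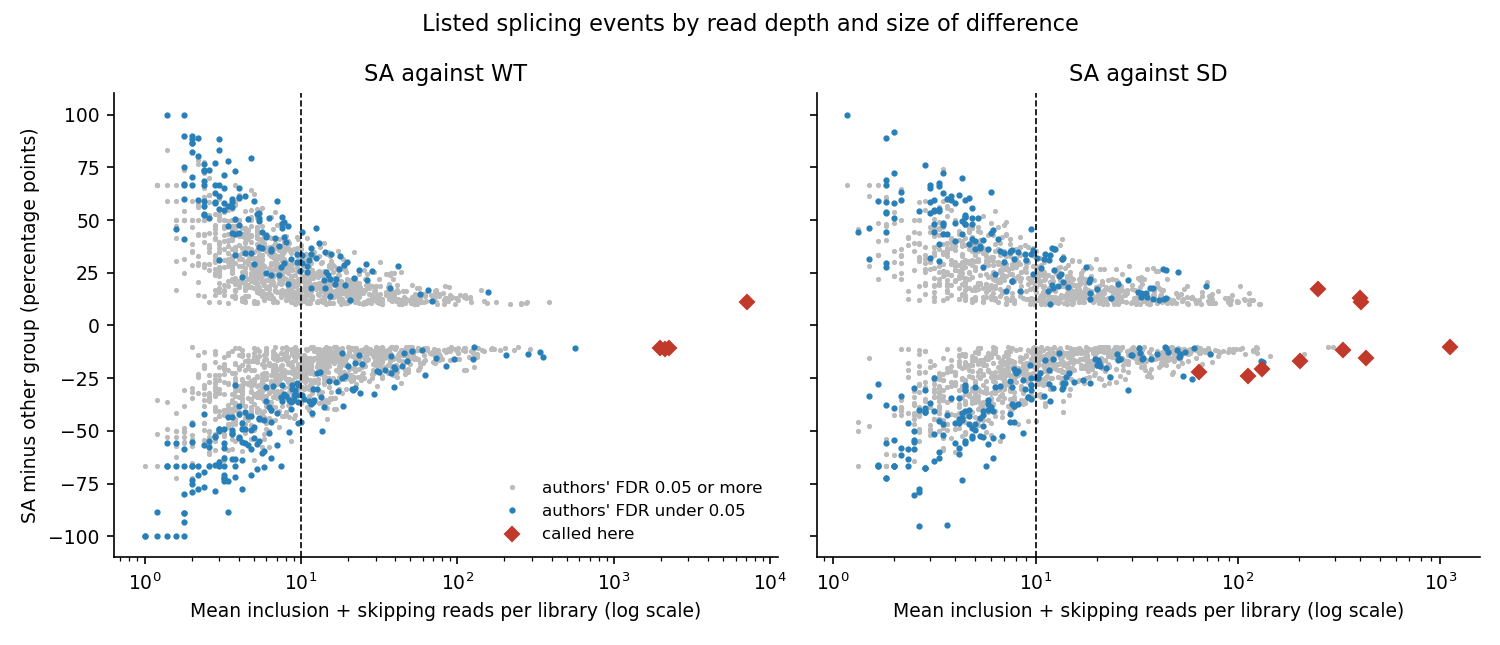
SA minus the other group in percentage points against the mean inclusion plus skipping reads per library on a log scale, for every listed event; blue marks an authors' FDR under 0.05, red diamonds the events called here and the dashed line the filter of 10 reads. Of the events past the authors' threshold, 227 for SA against WT and 217 for SA against SD lie left of the line.

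Many listed events had few reads. Of the listed events, 1270 (55.6%) for SA against WT and 1114 (55.0%) for SA against SD fell under the filter of 10 reads. They held 227 (69.8%) and 217 (66.0%) of the events past the authors' threshold. The median absolute difference was 33.2 points under the filter, 16.3 points in tested events and 13.5 points with at least 20 reads in every library for SA against WT. For SA against SD these medians were 30.5, 15.5 and 13.4 points.

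The comparisons share the SA libraries, and 541 events were listed in both tables, 521 in the same direction. No event was called in both by the limma-moderated test. Past an FDR of 0.05 in both of the authors' deposited tables and through the read filter were 9 events of 9 genes, each in the same direction. Higher in SA were RPGR, MYO5B, EDRF1, CSGALNACT2 and AMN1, and lower were BAZ1A, GATAD2A, NDUFA3 and PTOV1. BAZ1A and RPGR alone had at least 20 reads in every library of both tables, and the lowest library of the others held 4 reads (AMN1) to 11 reads (NDUFA3 and GATAD2A). MYO5B, a myosin motor of vesicle transport, had a 100% inclusion level in SA, 67.0% ± 9.84 (SD, n = 2) in WT and 68.1% ± 1.31 (SD, n = 3) in SD. NDUFA3, a subunit of respiratory complex I, had 66.8% ± 13.6 (SD, n = 3) in SA, 96.3% ± 5.24 (SD, n = 2) in WT and 91.3% ± 8.36 (SD, n = 3) in SD. Of the tested SA against WT events, 20.2% were also listed for SA against SD, and 99.5% of these ran in the same direction. Simulated unchanged groups, both set against one simulated SA group, gave 15.8% and 99.7%. The simulated lists came from another test and read filter than the observed ones, so these shares are not measured alike. Independent lists of these lengths would share 81.9 events, 40.9 of them in the same direction, against 541 found at any depth. The 3 SA libraries could not be split into parts of at least a pair each, so part of the overlap may come from the shared libraries.

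**Figure D5:**
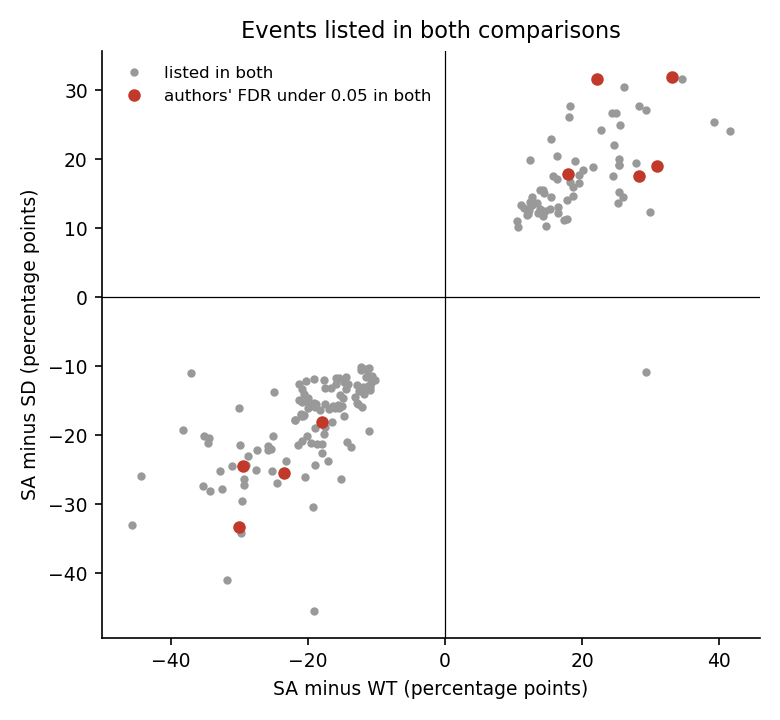
SA minus SD against SA minus WT, both in percentage points, for the 190 events listed in both tables with a mean of at least 10 reads per library in each; red marks the 9 past the authors' threshold in both. All but 1 of the points lie in the quadrants of equal sign.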

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

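Alternatives on the dispersion and the authors' FDR without a read filter were chosen after seeing the data, as were those on the authors' FDR for the lists and for both comparisons; the others were fixed before the data were examined. Adjusting over the listed events alone was the planned adjustment, and the one used in its place was chosen after seeing the data. No paired analysis was possible because the table cells carry no replicate numbers. The planned DESeq2 fit was not run, nor was the count of exon-body reads, which the tables lack. Dropping the minimum difference moved nothing, since every listed event exceeds it. The main counts were 4 events for SA against WT (1 higher in SA) and 10 for SA against SD (3 higher). limma on the logit of inclusion levels called 0 in both comparisons, 0 higher. The authors' FDR gave 98 (40 higher) and 112 (50 higher), and 325 (142 higher) and 329 (146 higher) without the read filter. Without the filter the test called 1 and 6 events, and at a minimum of 20 points it called 0 (0 higher) and 3 (0 higher). Adjusting over the listed events alone gave 6 and 140 (67 higher) events, and one dispersion for all events gave 8 and 10. Each event called here also passed the authors' FDR. With a library left out, the counts ran from 0 to 7 (0 to 2 higher) for SA against WT and from 0 to 10 (0 to 3 higher) for SA against SD; where 1 WT library remained, it was assumed to vary like the others. All directions of the called events were kept in each of these. No event was called against WT without SA replicate 3 or against SD without SA replicate 2. In these fits the prior degrees of freedom of the dispersion fell to 3.94 and 7.27, from 9.02 and 227 with all libraries. Whether that fall, rather than the library itself, removed the calls was not tested. The SRRM2 difference stayed between −11.1 and −10.6 points with a library left out. At −10.8 points it was not called by limma on logits (adjusted p = 1) or without the read filter (adjusted p = 0.148). Over the alternatives its adjusted p ranged from 1.98e-26 with one dispersion for all events to 1. The number of events called in both comparisons was 0 without SA replicate 1; without SA replicate 2 or 3 one comparison had no call, which fixed it at 0. It was 9 by the authors' FDR and 39 by it without the read filter. The median difference of cassette exons ran from −10.2 to −8.85 points against WT and from −9.91 to −8.13 points against SD with a library left out. With all libraries it was −11.1 and −10.8 points, outside these ranges. The events were selected on the difference with all libraries, which by itself draws the other values toward a smaller size. For retained introns the median ran from 13.1 to 14.2 and from 8.01 to 11.6 points with a library left out. Without the read filter the median of retained introns was 14.5 points against WT and −10.6 points against SD. Against SD 36 of 74 listed introns were higher in SA, beside 15 of 26 tested ones, so the median changed sign. With 20 reads in every library the median of retained introns was 13.9 points against WT. Of the named events, none changed sign with a library left out, but the differences of 5 (TCOF1, SH3GLB2, NR2C1, RPS6KA2 and DPCD) moved by over 1.5 times. No gene list passed with 20 reads in every library, by the authors' FDR or with both, and no exon property passed with 20 reads in every library. Simulated 10-point changes were missed at most depths, with 0 of 42 and 0 of 43 found at 10 to 50 reads and 0 of 8 and 1 of 7 above. Depth limited larger changes, as 1 of 46 and 1 of 42 simulated 20-point changes were found at 10 to 50 reads and 3 of 4 and 5 of 8 above. These simulations assumed the same dispersion for all events, which may make the shares found too favourable.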

Other observations

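The tests on SRRM2 reads and on events of both tables were chosen after their values had been seen; the regrouping of libraries was fixed before its result was seen. Some genes of the lists past the authors' threshold had events with few reads or a wide spread. A 24-nt exon of PICALM, a clathrin assembly protein, had 11.3% ± 9.07 (SD, n = 3) in SA and 41.7% ± 13.0 (SD, n = 3) in SD. It did not pass the limma-moderated test after adjustment. An exon of SRPK1, a kinase of SR proteins, had 38.2% ± 8.08 (SD, n = 3) in SA and 6.91% ± 2.96 (SD, n = 3) in SD, on 11 or 12 reads per library. An exon of RSRC1 had 89.9% ± 9.37 (SD, n = 3) and 56.0% ± 16.3 (SD, n = 3).

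Events past the authors' threshold often rested on few reads. Under the read filter, a Fisher's exact test of the pooled reads gave p over 0.05 for 129 of 227 such events (56.8%, Wilson interval 50.3% to 63.1%) in SA against WT. The same held for 110 of 217 (50.7%, Wilson interval 44.1% to 57.3%) in SA against SD. Among those that passed the filter it was 5 of 98 and 7 of 112. The events under the filter had a median of 19 and 25 reads over all libraries.

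The number of cassette exons under the p-value limit can be set against chance, for SA against SD only as an upper limit. A p-value under 0.05 is due to 2095 of 41899 cassette exons by chance in SA against WT, and the ranks implied by the deposited FDR reach at most 2342. For SA against SD the figures are 2317 by chance and at most 2310. The largest FDR deposited for these exons stood at its ceiling, where the implied rank equals the chance number at that p-value by construction. The value of 2310 is thus an upper limit alone, and its closeness to 2317 carries no meaning of its own. If the FDR is a Benjamini-Hochberg one, cassette exons up to that p-value were no more numerous than chance gives. That does not exclude changed exons among them. For the other types the highest implied ranks lay above the numbers due by chance. For mutually exclusive exons the figures were 288 and at most 621 against WT, and 331 and at most 488 against SD. Alternative 3′ splice sites had 269 and at most 377, and 285 and at most 354. Alternative 5′ splice sites had 170.3 and at most 235, and 178 and at most 238. Retained introns had 64.9 and at most 114, and 69.8 and at most 123.

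The SRRM2 exon is a pattern to follow up. Scaled by the reads of the other tested events, inclusion reads were 3.20 times as many in WT as in SA (counting interval 3.06 to 3.34), while the ratio of skipping reads was 0.926 (counting interval 0.769 to 1.11). A shift between forms at a constant amount of SRRM2 RNA is argued against by the ratio of all reads of the event, 2.98 (counting interval 2.86 to 3.11). More SRRM2 RNA of both forms in WT is argued against too, since skipping reads would then have risen with inclusion reads by about 3.20. A candidate explanation is that construct transcripts, if they carry the exon, add inclusion reads to those of the chromosomal gene and do so more in WT than in SA, as the skipping ratio of 0.926 would allow. This stays a hypothesis, because no value here separates construct reads, and a larger amount of RNA together with a shift between forms is also open.

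The events listed in both tables are another pattern. Of the tested SA against WT events 20.2% (Wilson interval 17.9% to 22.8%) were also listed for SA against SD, beside 15.8% in simulated unchanged groups. The simulation holds no real effect and one assumed dispersion, 1.3, and it lists events by its own test and read filter. It therefore excludes nothing, and the chance values of the shared SA libraries could account for much of the overlap. In the 193 shared events that could be tested, the median absolute difference between SD and WT was 3.07 points, with 0 events at an adjusted p under 0.05 and 1 at an unadjusted p under 0.05 in the limma-moderated test, but these events were selected for SA lying apart. In 1 of them, an exon of ENSG00000267120 on chromosome 19, SA lay between the other groups, and its SD against WT difference had an adjusted p of 0.678 in the limma-moderated test. An effect of the SA construct and a property of its sorted clone cannot be told apart, since the labels give no clone for any sample.

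For SA against SD, the 6 libraries can be split in 10 ways, too few for a share under 0.05. The real split gave 10 called events and the highest of the others 0, with 1 split reaching the real count, in a table whose events were selected on the real split.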
